A study of Mus musculus with 12 samples.

How the data were processed

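Gene expression was measured on Illumina mouse bead arrays in hematopoietic stem cells (HSCs) sorted from bone marrow. The gate took cells that were CD150-positive, CD48-negative, Sca-1-positive, c-Kit-positive and lineage-negative. There were 12 arrays, in 6 groups of 2 biological replicates each. Per the labels, each array held RNA of 200 sorted cells, isolated with Trizol, amplified in 2 rounds with the RiboAmp HS kit and labelled with biotin by in vitro transcription in the last round. The labels call the arrays of a group biological replicates and do not say whether these came from separate mice or pools, so p-values of single genes measure the spread between these samples.

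Per the file headers, the authors deposited a probe intensity and a detection p-value for each probe and array, in a non-normalized table for replicate 1 and another for replicate 2. The deposited intensities were linear and not background-subtracted, with medians from 40.8 to 49.8. The scanner software and the way the detection p-value was made are not given in the sources used here. The authors also deposited a table of processed intensities. Judged from its values, it was linear, not background-subtracted, not centred, and quantile normalized within each replicate number separately: its column medians were 45.3 to 45.4 for replicate 1 and 44.5 for replicate 2, and each column ranked the probes as its own array did (rank correlation at least 0.99999). Which software made it stays unknown. That table lacked 7 values and served as an alternative only. The number of value columns matched to no array was 0.

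The table of replicate 1 had 46643 lines and that of replicate 2 had 46632, over 46632 distinct probes. The 11 probes listed more than once were averaged. In the platform annotation used here, 29976 probes had 1 gene symbol, 10 had several and 16646 had none, and no gene was named from the latter kinds. Gene IDs were looked up in a RefSeq gene table of assembly GRCm38.p6, which held 29921 of them and changed 0 symbols. No genome build is named in the sources used here, so no coordinates are printed.

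Intensities were background-corrected with normexp from the detection p-values, with an offset of 16, quantile normalized over the 12 arrays and expressed as log2 (neqc in limma 3.58.1, R 4.3.3). Probes with a detection p-value under 0.05 on both arrays of at least 1 group were kept: 13512 probes, of which 10246 had 1 symbol, for 8374 genes. A probe kept through 1 group alone tends to lie higher in that group. Counts of list members that lie higher are therefore in part set by this filter. A gene is represented by its kept probe with the highest mean. Of the 1542 genes with more than 1 kept probe, 649 had probes that differed in sign for winner against loser, so a single probe's value need not hold for every transcript of its gene. Where a probe was not detected on either array of a group, that group has only a bound. Its contrast is then given as "at least N-fold", the other group's mean against the mean of, per array, the higher of the lowest detected value and the probe's own value. List medians use the fitted values of all members, also of those not detected in a group.

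A limma model with a mean for each of the 6 groups (6 residual degrees of freedom) gave 14 comparisons: 9 between pairs of groups, 2 interactions and 3 averages. P-values were adjusted by the Benjamini-Hochberg method over the 13512 probes, with a threshold of 0.05. The number of arrays limits the precision: the median standard error of a difference between groups was 0.44 log2. Each "± SD" below is over 2 arrays.

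Gene and marker lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over 25 lists per comparison, and again with camera's estimated correlation and with fry, which asks whether a list's genes move, on balance, one way. Camera sets a list's genes against all other genes. At the preset correlation its p-value rests on that assumed correlation, and a small one does not measure agreement between samples. There were 26 lists. They covered p53 targets, senescence and cell cycle inhibitors, S phase, G2 and mitosis, DNA repair and checkpoint, apoptosis, HSC identity, Myc targets and ribosome biogenesis, ribosomal proteins, oxidative phosphorylation, interferon response, immediate early genes, heat shock and unfolded protein, oxidative stress defence, NF-kB and inflammation, TGF-beta response and sex-linked transcripts. They also covered markers of erythroid, megakaryocyte, granulocyte and monocyte, mast cell and basophil, B lineage, T and NK, macrophage and dendritic, progenitor, and stromal and endothelial cells. The sex-linked list had 4 measured members, under the minimum of 5, and was not tested. The groups, comparisons, lists, the rule for named genes and most alternatives were fixed before the data were examined.

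The genes named were, per comparison and direction, the 10 largest differences among probes past the threshold with the same sign in both replicates, filled up to 5 by the smallest p where fewer passed. List members past the threshold were named too, or 3 members by smallest p of a list that camera called, along with 11 fixed genes. Acsl4, Pias1 and H2-Ea, called under single alternatives, fall outside this rule and were chosen after their values were seen. Of the fixed genes, Trp53, Bax and Ly6a were not analysed here, so the mutant p53 itself was not checked. Probes for Cdkn1a and Cdkn2a were not kept by the detection filter.

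On simulated data for winner against loser over 13512 probes, with 50 probes at each size, the model recovered 46% of changes of 2 log2 units, 80% of 3, 74% of 4 and 96% of 6, and called 8 of 13312 unchanged probes. All 5 shifted lists and 0 of 15 unshifted lists were called by camera at the preset correlation, by camera with an estimated correlation and by fry. The simulated noise was normal and independent between genes, took its spread from the fitted model and held no difference between the deposited tables. These counts therefore do not show how the list tests behave where genes vary together. Nor need the shares recovered hold for the real arrays, where the smallest adjusted p for winner against loser was 0.292. Counts of 0 genes below thus do not exclude changes of these sizes.

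Alternatives covered the replicate number as a block, no background correction, median scaling in place of quantile normalization, separate normalization of each deposited table with the block, the authors' processed intensities with the block, no detection filter, detection p-value under 0.01 on all 12 arrays, array weights, limma's trended and robust prior, all kept probes of a gene averaged, each array left out in turn, the 2 dimmest arrays left out together, and array brightness as a covariate. Brightness was the log2 95th percentile of raw intensity. The authors' intensities were tested only with the block because the tables had been normalized separately.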

Results

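The series asks how HSCs that express mutant p53 and wild-type (WT) HSCs fare beside each other in the marrow of irradiated mice. In mosaic mice, cells with mutant p53 (mp53) carried GFP and WT cells did not, so the populations could be told apart. After 2.5 Gy, the WT cells of mosaic mice are labelled losers of the competition and the mp53 cells winners. Non-competing controls came from irradiated mice that were WT or mp53 throughout, 3 weeks after exposure like the other irradiated groups. WT and mp53 cells of unirradiated mosaic mice made up the remaining 2 groups. Each of the 6 groups had 2 arrays.

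The arrays differed in brightness. The 95th percentile of raw intensity ran from 82.3 (mp53 cells of unirradiated mosaic mice, replicate 1) and 107 (loser, replicate 1) to 1079 (winner, replicate 2), and 8968 to 13489 probes (19.2% to 28.9%) were detected per array. The 2 arrays of a group correlated at 0.768 (mp53 cells of unirradiated mosaic mice) to 0.920 (winner), and the median was 0.869. Arrays of different groups in the same deposited table correlated at a median of 0.924. Because each table held every group once, a term for the table leaves each difference as it is and changes only its error.

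At the level of single genes, limma called 0 of 13512 probes in each of the 14 comparisons, with or without the table as a block. Probes with an unadjusted p under 0.05 numbered 1853 for winner against loser, 1800 for irradiation in mp53 cells of mosaic mice and 2101 for the interaction of irradiation with genotype, against 675.6 by chance. Single arrays moved these counts. Winner against loser had 895 without loser replicate 1, 1030 without winner replicate 1 and 897 without winner replicate 2. Irradiation in mp53 cells of mosaic mice had 624 and 4197 without unirradiated mp53 replicates 1 and 2, and 814 and 835 without winner replicates 1 and 2. The interaction had 1106 and 4056 without unirradiated mp53 replicates 1 and 2, 1179 without unirradiated WT replicate 1, 1156 without loser replicate 1 and 1085 without winner replicate 2. The other comparisons had 106 to 1051. With the table as a block, these 3 had 3552, 3614 and 3940 and the others 251 to 2054, among them loser against non-competing WT with 1357 in place of 551, mp53 against WT unirradiated with 1715 in place of 591 and irradiation in non-competing mp53 with 1279 in place of 441. Genes are therefore named below with their values, and lists of genes are given for each comparison. All list calls below are those of camera at the preset correlation: with an estimated correlation camera called 0 lists in each comparison, and the adjusted p is given beside each. With the table as a block, other splits within tables gave medians of 5, 5 and 7 called lists for averaged mp53, irradiation and competition. The actual groups gave 8, 8 and 3, so a call at the preset correlation does not by itself show a difference between groups.

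Winner and loser HSCs came from the same kind of irradiated mosaic mouse and differ in genotype and competitive outcome. In replicate 1 they also differed in sex-linked transcripts, with the Y-linked Eif2s3y at 8.77 in winners and 4.33 in losers and Xist at 6.36 and 8.11. Winner cells had lower levels of genes that mark or maintain HSCs. Ndn, which encodes the growth suppressor necdin, stood at 5.47 ± 0.11 log2 in winners and 9.81 ± 0.14 in losers (difference -4.34, SE 0.53). Fgd5, a guanine nucleotide exchange factor used to mark HSCs, was at 4.73 ± 0.04 against 7.29 ± 0.48, and Zfp521, a zinc finger regulator of immature blood cells, at 5.25 ± 0.25 against 7.25 ± 0.27. In the HSC identity list, 27 of 31 measured members lay lower in winners (median -1.30, and -1.40 and -1.53 within replicates 1 and 2). Of these, 13 passed when adjusted over the list alone, Ndn at 0.000782 and Fgd5 and Zfp521 at 0.00846, and 0 passed over all genes (adjusted p = 4.86e-10 for the list, adjusted p = 0.285 with an estimated correlation).

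Markers of mature blood cells lay higher in winners. Irf8, a transcription factor of monocytes and dendritic cells, was at least 11.5-fold higher, and Blnk, the adaptor of the B cell receptor, at least 9.32-fold. Csf3r, the receptor for granulocyte colony-stimulating factor, was at 7.14 ± 0.20 against 4.58 ± 0.31, and Il7r, the interleukin-7 receptor of lymphoid progenitors, was at least 2.46-fold higher. All 19 measured granulocyte and monocyte markers were higher (median 2.31, and 2.92 and 1.55 within replicates). The same held for 9 of 10 B lineage markers (1.63, and 2.21 and 0.78), 15 of 16 erythroid markers (1.52, and 1.58 and 0.87), 8 of 11 macrophage and dendritic cell markers (1.40, and 1.52 and 1.04) and 8 of 11 T and NK markers (0.96, and 0.98 and 0.56). Adjusted over the list alone, 8 B lineage, 3 macrophage and dendritic cell and 2 granulocyte members passed, and 0 over all genes. The filter kept 10 of 16 B lineage genes on the array, among them Cd79a, which was detected in winners only. Camera's adjusted p was 3.48e-06 for granulocytes and monocytes, 2.04e-06 for the B lineage, 0.000114 for erythroid cells, 0.00292 for macrophages and dendritic cells and 0.00612 for T and NK cells. With an estimated correlation the adjusted p was 0.322 for the granulocyte and monocyte list and 0.285 for the other 4.

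Progenitor, mitotic and inflammatory genes were higher in winners as well. Cd48, whose product the sort excluded, was higher by 2.04 (SE 0.70), while Cd34, a surface marker of progenitors, was at 6.04 ± 0.19 against 7.71 ± 0.04. In the progenitor list, 8 of 11 members were higher (median 1.60, and 1.88 and 1.05 within replicates), and adjusted over the list alone 7 passed upwards and 1 downwards (adjusted p = 0.00292, adjusted p = 0.285 with an estimated correlation). Tacc3, a spindle protein, was at 6.95 ± 0.09 against 5.33 ± 0.30, and 21 of 22 G2 and mitosis genes were higher (median 0.93, and 1.28 and 0.53, adjusted p = 5.87e-05, adjusted p = 0.285 with an estimated correlation). Among 16 NF-kB and inflammation genes, 13 were higher (median 0.68, and 0.83 and 0.60, adjusted p = 0.00226, adjusted p = 0.285 with an estimated correlation). They included Tnfaip3, an inhibitor of NF-kB signalling (difference 1.49, SE 0.53), and Il1b, the cytokine interleukin-1 beta, at least 7.99-fold higher.

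Genes of protein synthesis lay lower in winners. Nolc1, a nucleolar protein, differed by -1.50 (SE 0.41) and Ncl, nucleolin, by -1.22 (SE 0.46). In the list of Myc targets and ribosome biogenesis, 18 of 20 members were lower (median -0.50, and -0.54 and -0.48 within replicates, adjusted p = 0.0137, adjusted p = 0.322 with an estimated correlation). Of 47 ribosomal protein genes, 44 were lower (median -0.45, and -0.38 in each replicate, adjusted p = 0.00109, adjusted p = 0.33 with an estimated correlation). Rpl3l, a muscle paralog in that list, was higher by 2.72 (SE 1.02). Outside the lists, Prkg1, a cGMP-dependent kinase, was at 6.25 ± 0.36 against 9.51 ± 0.31 and Il11ra2, an interleukin-11 receptor subunit, at 8.01 ± 0.23 against 9.92 ± 0.21. Lat2, an adaptor of immune receptor signalling, was at least 3.54-fold higher in winners and Rasgrp3, a Ras activator of B cells, at least 2.08-fold.

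Several programmes tied to p53 did not pass between winner and loser. The 15 measured p53 targets had a median of -0.07, against a mean of 0.24 (adjusted p = 0.808). Mdm2, the p53 target that degrades p53, was at 9.49 ± 0.15 in winners and 9.84 ± 0.11 in losers. Ccng1, another p53 target, differed by -0.47 (SE 0.52), and by 0.23 without loser replicate 1. Senescence and cell cycle inhibitors had a median of 0.37 (adjusted p = 0.158), with 2 members up and 2 down adjusted over the list alone. Their member Cdkn2c, a CDK inhibitor, differed by 0.62 (SE 0.36), and by -0.12 under median scaling, where the median of all probes was -0.72. Apoptosis genes had a median of 0.15 (0.232), DNA repair 0.11 with a mean of -0.00 (0.996), S phase 0.19 (0.254) and the interferon response 0.05 (0.655). Medians were 0.74 for immediate early genes (0.0518), 0.25 for oxidative phosphorylation (0.0796), 0.36 for oxidative stress defence (0.0835), 0.47 for heat shock and unfolded protein (0.307) and 0.12 for the TGF-beta response (0.224). Among markers they were 1.68 for mast cells and basophils (0.0718), -0.43 for megakaryocytes (0.418) and -0.16 for stroma and endothelium (0.996).

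For winner against loser, limma's smallest adjusted p for a gene was 0.292, and with its trended and robust prior it called 3 genes, Ndn, Klra9 and Rasgrp3 (adjusted p = 0.0425). Camera called 11 of 25 lists, 8 higher and 3 lower, fry called 0, and the table as a block added oxidative phosphorylation (adjusted p = 0.0168). With brightness as a covariate the G2 and mitosis median turned to -0.08 and the granulocyte and monocyte and erythroid medians stood at 0.51 and 0.61, all without a call, while HSC identity stayed called at -0.92. Under median scaling, where the median of all probes was -0.72, the Myc target and ribosomal protein calls ended (adjusted p = 0.435 and 0.0947), as did that of T and NK cells.

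**Figure D1:**
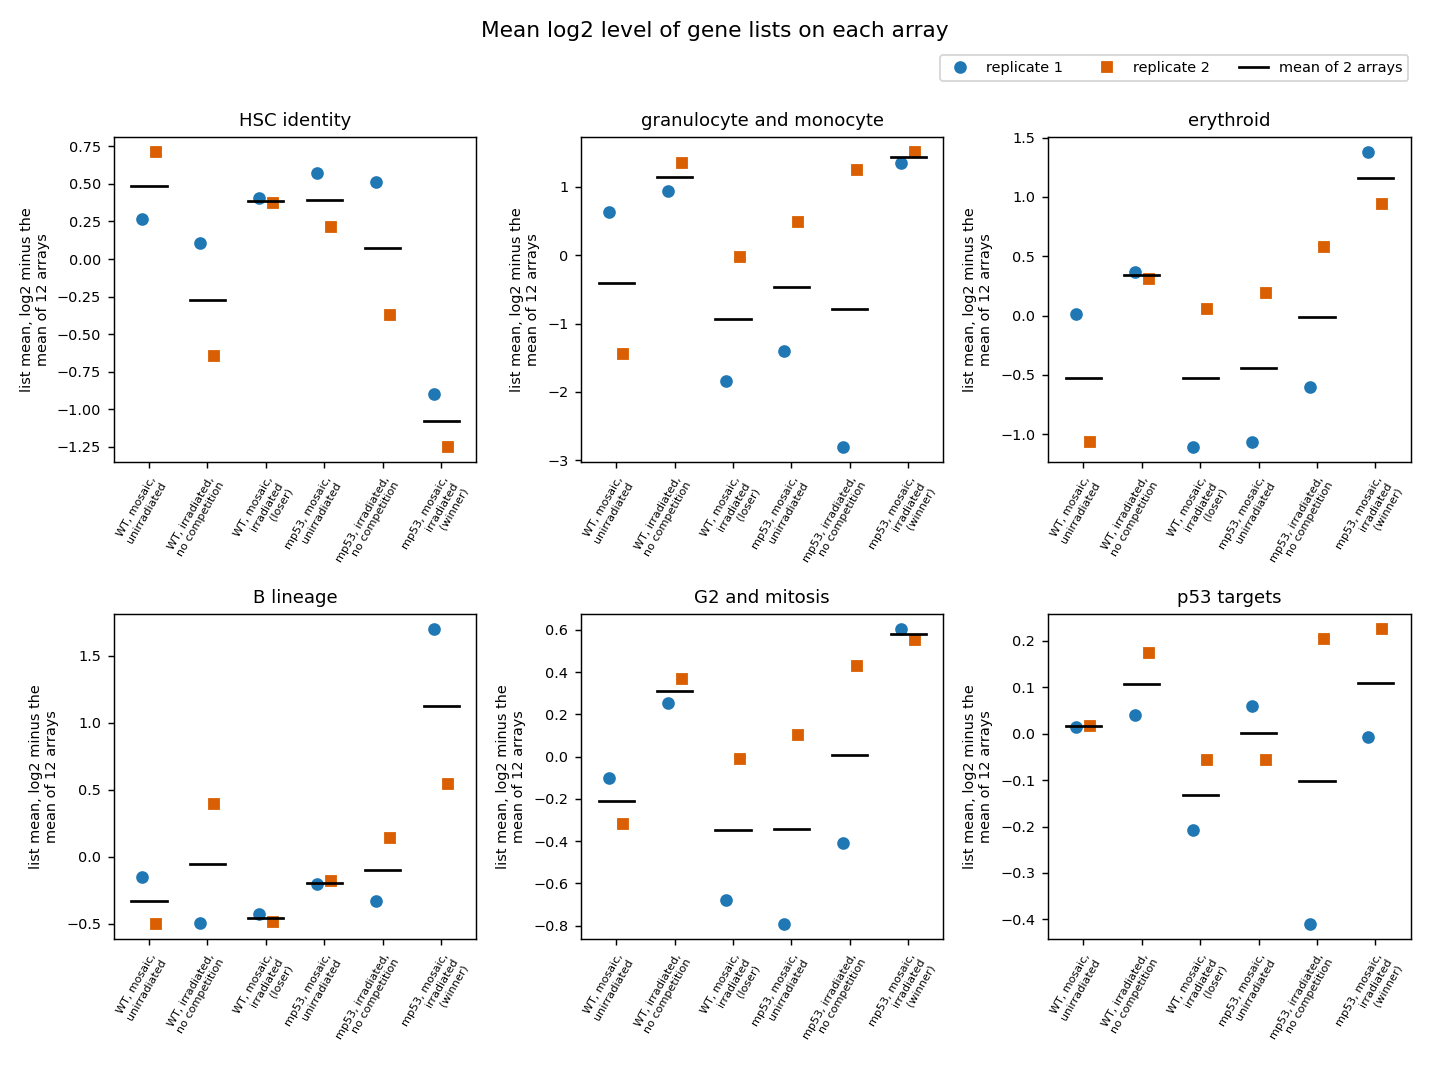
Mean log2 intensity of 6 gene lists on each array, relative to the mean over the 12 arrays, by group. Circles are replicate 1, squares replicate 2 and lines the mean of both; winner arrays sit at -0.90 and -1.25 for HSC identity, below the other 10 arrays, which range from -0.64 to 0.71.

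Losers were also set against non-competing WT HSCs, both irradiated. The controls came from mice that were WT throughout, so this contrast joins the presence of mp53 neighbours with the kind of mouse. In replicate 1 the arrays also differed in Eif2s3y (4.33 in losers, 9.43 in controls) and Xist (8.11 and 4.88). Loser cells lay above non-competing WT cells in HSC genes and below them in myeloid and mitotic genes. Ndn was at 9.81 ± 0.14 against 8.24 ± 0.92 and Hoxa7, a homeobox factor, at 8.47 ± 0.90 against 6.77 ± 0.58. In the HSC identity list, 26 of 31 members were higher (median 0.70, and 0.30 and 0.97 within replicates, adjusted p = 1.09e-05). All 19 granulocyte and monocyte markers were lower (median -2.08, and -2.43 and -1.38, adjusted p = 2.3e-07), such as Csf3r at 4.58 ± 0.31 against 6.39 ± 0.53. With an estimated correlation the adjusted p was 0.543 for both lists. Of 22 G2 and mitosis genes, 21 were lower (median -0.63, and -0.89 and -0.30, adjusted p = 0.000147, adjusted p = 0.543 with an estimated correlation), among them Kif23, a kinesin of cell division (difference -0.93, SE 0.48).

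Progenitor markers were lower in losers in 10 of 11 cases (median -1.18, and -1.46 and -0.86 within replicates, adjusted p = 0.00041, adjusted p = 0.498 with an estimated correlation). Irf8 was at least 4.39-fold lower, and Cd53, a leukocyte tetraspanin, was at 7.51 ± 0.48 against 9.90 ± 0.29. NF-kB and inflammation genes were lower in 14 of 16 cases (median -0.55, and -0.34 and -0.38, adjusted p = 0.0198, adjusted p = 0.498 with an estimated correlation). Myd88, the adaptor of Toll-like receptors, differed by -1.23 (SE 0.47). Erythroid markers were lower in 13 of 16 cases (median -0.47, and -0.66 and -0.14, adjusted p = 0.0329, adjusted p = 0.581 with an estimated correlation). Myc targets were higher in 18 of 20 cases (median 0.41, and 0.21 and 0.50, adjusted p = 0.0254, adjusted p = 0.581 with an estimated correlation), and ribosomal proteins in 43 of 47 (median 0.23, and 0.04 and 0.36, adjusted p = 0.0198, adjusted p = 0.636 with an estimated correlation). By smallest p, Slc25a32, a mitochondrial folate carrier, was at 6.18 ± 0.31 against 4.50 ± 0.25, and Pxmp2, a peroxisomal membrane protein, was lower by 1.65 log2 units (difference -1.65, SE 0.32).

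Over these 8 lists, 0 members passed adjusted over the list alone or over all genes, and limma had 551 probes at an unadjusted p under 0.05 (320 without loser replicate 1 to 868 without either unirradiated mp53 array, smallest adjusted p 0.912). P53 targets (median -0.09, adjusted p = 0.533) and senescence genes (-0.09, 0.222) did not pass, and Mdm2 differed by 0.03 (SE 0.29). Without WT replicate 2 of the non-competing mice 3 lists were called, with HSC identity at 0.34 and not called, and without loser replicate 2 there were 5. Without the 2 dimmest arrays the G2 and mitosis median was -0.28 (adjusted p = 0.0692), and under median scaling, where the median of all probes was 0.47, the erythroid median turned to 0.13.

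Winners were compared with non-competing mp53 HSCs, again both irradiated. The controls came from mice that were mp53 throughout, so competition is again joined with the kind of mouse. In replicate 1 the arrays also differed in Eif2s3y (8.77 in winners, 4.23 in controls) and Xist (6.36 and 7.94). Winner cells lay lower in HSC genes. Ndn was at 5.47 ± 0.11 against 8.91 ± 0.89, Sult1a1, a sulfotransferase, at 5.07 ± 0.23 against 7.11 ± 0.17, and Robo4, a guidance receptor of HSCs and endothelium, differed by -2.85 (SE 0.69). In the HSC identity list, 28 of 31 members were lower (median -0.91, and -1.41 and -0.74 within replicates), 7 of them when adjusted over the list alone and 0 over all genes (adjusted p = 5.31e-16, adjusted p = 0.147 with an estimated correlation). B lineage markers were higher in 9 of 10 cases (median 1.30, and 2.10 and 0.42), with 3 passing adjusted over the list alone, Fcrla, an Fc receptor-like B cell protein, Il7r and Cd79a, a chain of the B cell receptor (list adjusted p = 7.03e-11, adjusted p = 0.147 with an estimated correlation). Cd79a was detected on the 2 winner arrays only, so the filter kept it through the group where it is high.

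Other lineages were higher mainly in replicate 1. There the granulocyte and monocyte list mean was -2.81 in non-competing mp53 cells, against 1.25 in their replicate 2 and 1.35 and 1.51 in winners. Granulocyte and monocyte markers had a median of 2.04 over 19 of 19 members, but 4.12 and 0.38 within replicates 1 and 2 (adjusted p = 5.91e-11, adjusted p = 0.239 with an estimated correlation). Erythroid markers had a median of 0.78 (1.15 and 0.36, 16 of 16 higher, adjusted p = 1.27e-05, adjusted p = 0.213 with an estimated correlation). For macrophages and dendritic cells it was 1.04 (1.85 and 0.15, adjusted p = 2.03e-05, adjusted p = 0.147 with an estimated correlation) and for progenitor markers 0.94 (1.92 and 0.08, adjusted p = 0.00126, adjusted p = 0.213 with an estimated correlation). Mast cell and basophil markers had a median of 1.00 (1.71 and 0.28) and T and NK markers 0.55 (0.88 and -0.02), with adjusted p of 0.016 and 0.0271, and adjusted p = 0.239 and 0.323 with an estimated correlation. Alas2, the first enzyme of heme synthesis in red cells, differed by 2.45 (SE 0.76).

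G2 and mitosis genes had a median of 0.64 (1.04 and 0.19, 20 of 22 higher, adjusted p = 1.86e-05, adjusted p = 0.239 with an estimated correlation), with the mitotic kinase Aurka at 0.92 (SE 0.46). NF-kB and inflammation genes had a median of 0.39 (0.53 and 0.16) and oxidative stress defence 0.31 (0.49 and 0.09), each with an adjusted p of 0.0115 (adjusted p = 0.147 with an estimated correlation). Immediate early genes had a median of 0.33 (0.78 and -0.08, adjusted p = 0.0271, adjusted p = 0.323 with an estimated correlation). Ribosomal proteins were lower in 40 of 47 cases (median -0.37, and -0.63 and 0.04, adjusted p = 8.06e-05) and Myc targets in 18 of 20 (-0.38, and -0.82 and 0.07, adjusted p = 0.00966), both with adjusted p = 0.323 with an estimated correlation. P53 targets (0.06, adjusted p = 0.327) and senescence genes (0.03, 0.153) did not pass, Mdm2 differed by -0.07 (SE 0.29) and Cd48 by 1.78 (SE 0.70).

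Of the 14 lists called (11 higher, 3 lower, 394 probes at an unadjusted p under 0.05 in limma, 89 and 1237 without replicates 1 and 2 of the non-competing mp53 group), 5 were called without replicate 1 of the non-competing mp53 group, in which the G2 and mitosis, granulocyte and monocyte, and T and NK medians turned to -0.01, -0.00 and -0.08, and 9 without winner replicate 1. With the table as a block, immediate early genes, mast cells and basophils, and T and NK cells lost their call (adjusted p = 0.0521, 0.0542 and 0.0527) and oxidative phosphorylation gained one (0.016).

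**Figure D2:**
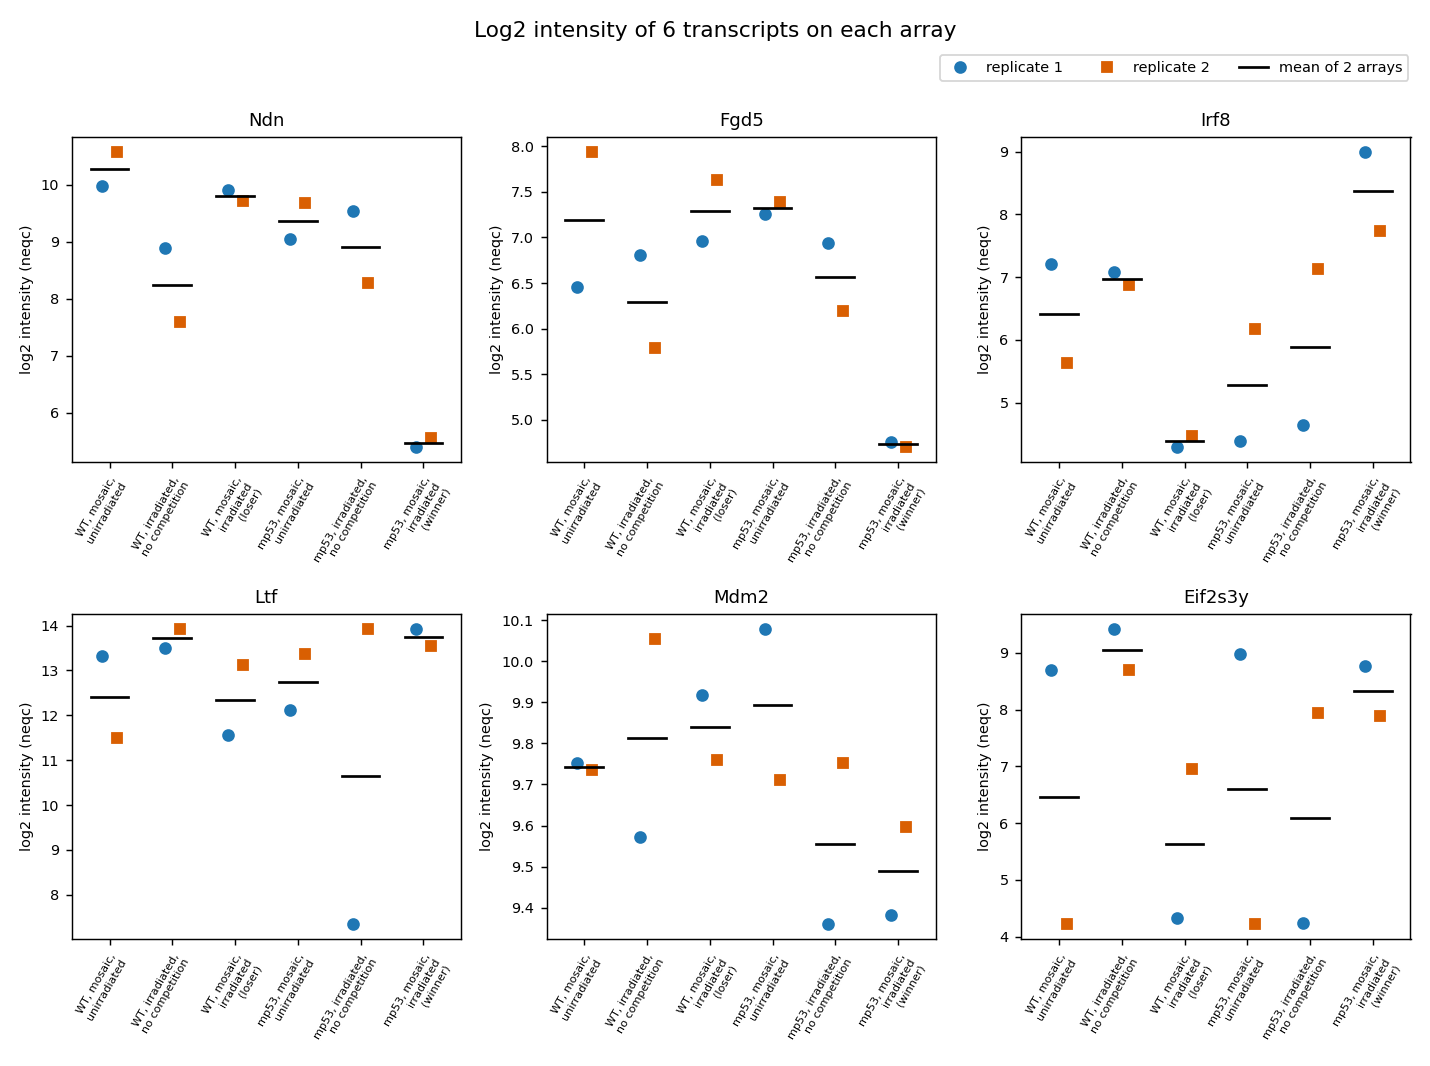
Log2 normalized intensity of Ndn, Fgd5, Irf8, Ltf, Mdm2 and Eif2s3y on each array, by group, with replicate 1 as circles, replicate 2 as squares and the group mean as a line. Ndn lies at 5.39 and 5.55 in winners and between 7.58 and 10.58 on the other 10 arrays, while the granulocyte protein gene Ltf lies at 7.35 in replicate 1 of the non-competing mp53 group and at 11.49 or more elsewhere.

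Genotype alone was compared without irradiation and with irradiation but no competition. In unirradiated mosaic mice, mp53 and WT HSCs differed in 0 of 25 lists (0 with an estimated correlation and 0 by fry), and limma had 591 probes at an unadjusted p under 0.05. Without unirradiated mp53 replicates 1 and 2 it had 194 and 3286, and without unirradiated WT replicates 1 and 2 it had 392 and 337. Some list means went opposite ways within the replicates. For granulocytes and monocytes they were -1.41 in mp53 and 0.63 in WT cells of replicate 1, and 0.48 and -1.44 in replicate 2. For HSC identity they were 0.58 and 0.26, then 0.21 and 0.71. The 0 calls therefore do not show that the genotypes were alike. The HSC identity median was -0.09 (adjusted p = 0.904) and that of p53 targets -0.04 (0.969), while Mdm2 differed by 0.15 and Cd48 by -1.15 (0.00 under median scaling, where the median of all probes was 0.68). By smallest p, Samd14, a protein of erythroid progenitor signalling, was at 8.96 ± 0.25 in mp53 cells and 7.60 ± 0.08 in WT cells, Tnfrsf21, a death receptor, was higher by 1.43 (SE 0.36), and Nsun2, an RNA methyltransferase, differed by -1.49 (SE 0.31). Without WT replicate 2 of the unirradiated mice 2 lists were called.

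After irradiation without competition, mp53 HSCs lay below WT HSCs in myeloid genes. In replicate 1 the arrays also differed in Eif2s3y (4.23 in mp53 cells, 9.43 in WT cells) and Xist (7.94 and 4.88). All 19 granulocyte and monocyte markers were lower (median -1.87), by -3.60 in replicate 1 and -0.04 in replicate 2, and Ltf was at 10.64 ± 4.65 in mp53 cells and 13.71 ± 0.30 in WT cells. All 11 progenitor markers were lower (-0.57, and -1.16 and -0.04), as were 20 of 22 G2 and mitosis genes (-0.33, and -0.60 and 0.06), while 26 of 31 HSC identity genes were higher (0.33, and 0.48 and 0.20). Adjusted p was 2.26e-11, 0.00105, 0.00525 and 0.00105 in that order, and adjusted p = 0.701 with an estimated correlation for each. Hgf, hepatocyte growth factor, was at 7.08 ± 0.17 against 6.13 ± 0.15. Without replicate 1 of the non-competing mp53 group 1 list was called and the granulocyte and monocyte, G2 and mitosis and HSC identity medians turned to 0.23, 0.31 and -0.18, while without its replicate 2 there were 9 lists. Limma had 130 probes at an unadjusted p under 0.05 (87 without non-competing WT replicate 2 to 517 without non-competing mp53 replicate 2), and 0 list members passed adjusted over the list alone.

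Irradiated WT HSCs without competition, from mice that were WT throughout, had lower HSC genes than WT cells of unirradiated mosaic mice, a contrast that joins irradiation with the kind of mouse. Eif2s3y also differed in replicate 2, at 8.69 in irradiated and 4.23 in unirradiated cells. In 28 of 31 HSC identity genes irradiated cells lay lower (median -0.79, and -0.15 and -1.34 within replicates, adjusted p = 3.13e-10, adjusted p = 0.611 with an estimated correlation). Ndn was at 8.24 ± 0.92 against 10.28 ± 0.42. Granulocyte and monocyte markers were higher in 19 of 19 cases (1.57, and 0.24 and 2.93), erythroid markers in 12 of 16 (0.67, and 0.31 and 0.94) and G2 and mitosis genes in 21 of 22 (0.54, and 0.31 and 0.66), with adjusted p of 1.46e-06, 0.00266 and 9.36e-05. Ribosomal proteins were lower in 43 of 47 cases (-0.18, and 0.02 and -0.46, adjusted p = 0.00668, median 0.12 under median scaling, where the median of all probes was 0.41). With an estimated correlation the adjusted p was 0.634 for these 4 lists. Fry called the interferon response alone (median -0.28, adjusted p = 0.0318), which camera did not (0.0929). Cdkn2c was at 6.07 ± 0.56 in irradiated and 5.03 ± 0.01 in unirradiated cells. Limma had 236 probes at an unadjusted p under 0.05 (675 and 61 without non-competing WT replicates 1 and 2), and without WT replicate 2 of the unirradiated mice 2 lists were called.

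Irradiated mp53 HSCs without competition came from mice that were mp53 throughout and their unirradiated counterparts from mosaic mice, so that this contrast joins irradiation with the kind of mouse. It gave 0 called lists by camera at either correlation and 0 by fry, with 441 probes at an unadjusted p under 0.05 in limma (145 and 3179 without unirradiated mp53 replicates 1 and 2). HSC identity had a median of -0.36 (adjusted p = 0.1), and granulocyte and monocyte markers 0.16 with a mean of -0.32 (0.852). The arrays also differed in Eif2s3y, at 8.98 and 4.22 in unirradiated and 4.23 and 7.95 in irradiated cells (replicates 1 and 2). Wwtr1, a coactivator of the Hippo pathway, was lower by smallest p (difference -2.55, SE 0.52), as was Gprasp1, a receptor-sorting protein (difference -1.15, SE 0.27), and Wnk1, a kinase of ion transport, was at least 2.62-fold higher. Without replicate 1 of the non-competing mp53 group 8 lists were called and without its replicate 2 there were 2. Without replicate 2 of unirradiated mp53 cells there was 1 list and 1 gene, Pias1, a SUMO ligase (difference 3.86, adjusted p = 0.0299).

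In WT cells of mosaic mice, irradiated losers were compared with unirradiated cells. Eif2s3y differed here too, at 8.70 and 4.23 in unirradiated cells and 4.33 and 6.95 in losers (replicates 1 and 2). NF-kB and inflammation genes were lower in 14 of 16 cases (median -0.79, and -1.03 and -0.18 within replicates, adjusted p = 0.00276, adjusted p = 0.194 with an estimated correlation), the single list called. Tnfaip3 differed by -1.29 (SE 0.53) and the chemokine gene Ccl4 by -1.12 (SE 0.48). By smallest p, Foxa3, a forkhead factor, was lower (difference -2.20, SE 0.45), Cdc25b, a phosphatase that starts mitosis, was higher (1.27, SE 0.35), and Skil, a repressor of TGF-beta signalling, was at least 2.59-fold lower. The NF-kB median turned to 0.12 under median scaling, where the median of all probes was 0.68, and 0 lists were called without unirradiated WT replicate 1, 6 without its replicate 2 and 2 without either array of the non-competing mp53 or the winner group. Limma had 515 probes at an unadjusted p under 0.05 (240 without loser replicate 1 to 1035 without either unirradiated mp53 array), and fry called 0 lists.

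In mp53 cells of mosaic mice, irradiated winners lay below unirradiated cells in HSC genes. Their arrays of replicate 2 also differed in Eif2s3y (7.89 in winners, 4.22 in unirradiated cells). Ndn was at 5.47 ± 0.11 against 9.37 ± 0.44, and Cdkn1c, which encodes the CDK inhibitor p57 of quiescent HSCs, at 6.36 ± 0.23 against 9.74 ± 0.22. Of 31 HSC identity genes, 28 were lower (median -1.47, and -1.39 and -1.43 within replicates), 17 of them adjusted over the list alone and 0 over all genes (adjusted p = 1.14e-10, adjusted p = 0.358 with an estimated correlation). Higher were granulocyte and monocyte markers in 19 of 19 cases (2.01, and 2.63 and 1.22, adjusted p = 0.000196, adjusted p = 0.529 with an estimated correlation), B lineage markers in 9 of 10 (1.39, and 2.16 and 0.62, 6 adjusted over the list alone), macrophage and dendritic cell markers in 8 of 11 (1.44, and 1.62 and 0.62, 2 adjusted over the list alone), progenitor markers in 8 of 11 (1.35, and 1.87 and 1.15, 4 adjusted over the list alone) and erythroid markers in 15 of 16 (1.12, and 1.89 and 0.90). Adjusted p for the latter 4 lists was 5.09e-05, 0.0129, 0.00856 and 0.000334, and adjusted p = 0.358 with an estimated correlation.

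Dividing and respiring cell programmes were higher in irradiated mp53 cells of mosaic mice too. G2 and mitosis genes were higher in 21 of 22 cases (median 0.88, and 1.36 and 0.47), with Tpx2, a spindle assembly factor, at 8.48 ± 0.25 against 6.41 ± 0.13, and S phase genes in 17 of 22 (0.31, and 0.30 and 0.41), with the replication licensing factor Cdc6 at 7.96 ± 0.03 against 6.83 ± 0.13. Adjusted p was 0.000179 and 0.0129, and adjusted p = 0.358 with an estimated correlation for both. Oxidative phosphorylation genes were higher in 52 of 63 cases (0.43, and 0.56 and 0.25, adjusted p = 0.00668, adjusted p = 0.47 with an estimated correlation), and had a median of -0.01 without unirradiated mp53 replicate 1. Oxidative stress defence was higher in 12 of 16 cases (0.55, and 0.67 and 0.27, adjusted p = 0.0493, adjusted p = 0.358 with an estimated correlation), with Hmox1, heme oxygenase, at least 2.35-fold higher. Ribosomal proteins were lower in 35 of 47 cases (-0.38, and -0.31 and -0.38, adjusted p = 0.0073, adjusted p = 0.529 with an estimated correlation). Limma's 0 calls stood beside 1800 probes at an unadjusted p under 0.05, and without unirradiated mp53 replicate 2 there were 599 genes (241 higher, 358 lower) and 6 lists in place of 11. Leaving out unirradiated mp53 replicate 2 left that group with replicate 1 alone, the dimmest of the 12 arrays. With brightness as a covariate the granulocyte and monocyte and the oxidative phosphorylation medians turned to -0.01 and -0.06.

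Whether competition goes with different changes in the genotypes was tested as loser minus non-competing WT, minus winner minus non-competing mp53. Here too competition is joined with the kind of mouse. Ndn had the largest such difference among HSC genes named (5.01, SE 0.76), with Robo4 at 3.98 (SE 0.97) and Hoxa7 at 3.68 (SE 0.84), and 28 of 31 HSC identity genes were positive (median 1.51, and 1.48 and 1.71 within replicates, 13 adjusted over the list alone and 0 over all genes). Negative were granulocyte and monocyte markers in 19 of 19 cases (-4.22, and -6.47 and -1.68), B lineage markers (-1.63), erythroid markers (-1.58) and progenitor markers (-2.14, and -3.29 and -0.99). Adjusted p was 1.65e-11 for HSC identity, 4.71e-11 for granulocytes and monocytes, 5.5e-06 for the B lineage, 0.000198 for erythroid cells and 0.000187 for progenitors, and adjusted p = 0.287 with an estimated correlation for each. Camera called 11 lists in all, 3 higher and 8 lower, and limma 0 probes with 1051 at an unadjusted p under 0.05 (404 and 1750 without non-competing mp53 replicates 1 and 2).

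The interaction of irradiation with genotype in mosaic mice was winner minus unirradiated mp53, minus loser minus unirradiated WT. It takes in the Eif2s3y differences given above for irradiation in mp53 and WT cells of mosaic mice. HSC identity genes were negative in 25 of 31 cases (median -1.43, and -1.49 and -1.21 within replicates), Ndn at -3.42 (SE 0.76) and Cdkn1c at -3.63 (SE 0.99). Progenitor markers had a median of 2.28 (3.16 and 0.52), with Notch1, a receptor of lymphoid fate, at 2.97 (SE 0.91). Granulocyte and monocyte markers had 2.45, positive in replicate 1 (4.99) and negative in replicate 2 (-0.84), and Csf3r 3.76 (SE 0.91). Adjusted p was 9.87e-06, 0.00383 and 0.00198, and adjusted p = 0.466, 0.466 and 0.513 with an estimated correlation. Adjusted over the list alone, 1, 3 and 2 members passed, and 0 over all genes. Of the 9 lists called, 4 were called without unirradiated WT replicate 1, 4 without winner replicate 1 and 5 without unirradiated mp53 replicate 2, the last of which also gave 1285 genes (300 higher, 985 lower) where limma otherwise called 0, with 2101 at an unadjusted p under 0.05. Here too, without unirradiated mp53 replicate 2 the dimmest array stood alone for its group. With brightness as a covariate the granulocyte and monocyte median turned to -0.88.

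Averaged over the 3 pairs of groups (6 arrays against 6), mp53 cells had lower HSC identity genes than WT cells in 25 of 31 cases (median -0.37, and -0.14 and -0.64 within replicates, adjusted p = 6.3e-08), Ndn at -1.53 (SE 0.31), and B lineage markers higher in 10 of 10 (0.48, and 0.66 and 0.27, adjusted p = 6.3e-08). The HSC identity median differed between the averaged pairs: -1.30 for winner against loser, -0.09 unirradiated and 0.33, called higher, irradiated without competition. Erythroid (0.54, and 0.20 and 0.85), T and NK (0.26, and 0.24 and 0.49), macrophage and dendritic cell (0.45, and 0.17 and 0.74) and NF-kB genes (0.18, and 0.15 and 0.21) were higher, with adjusted p of 0.000292, 0.000244, 0.00972 and 0.0258. With an estimated correlation the adjusted p was 0.333 for these 6 lists. G2 and mitosis (0.16, and -0.01 and 0.35, adjusted p = 0.0392) and ribosomal proteins (-0.14, and -0.07 and -0.22, adjusted p = 0.0176) had an adjusted p = 0.587 with an estimated correlation. Of the 8 lists called, 3 were called without unirradiated mp53 replicate 2, 4 without unirradiated WT replicate 2, and 5 without either winner replicate 1 or non-competing mp53 replicate 2. Limma had 304 probes at an unadjusted p under 0.05 (166 without non-competing mp53 replicate 2 to 829 without unirradiated mp53 replicate 2), and 1 list member, Ndn, passed adjusted over the list alone.

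Averaged irradiation (8 arrays, 4 of them from mice that were not mosaic, against 4 from mosaic mice) went with lower HSC identity genes in 27 of 31 cases (median -0.65, and -0.37 and -0.96 within replicates, adjusted p = 3.13e-13, adjusted p = 0.497 with an estimated correlation). Ndn differed by -1.72 (SE 0.33) and Sult1a1 by -1.49 (SE 0.32), the 2 members that passed adjusted over the list alone, and Foxa3 by -1.80 (SE 0.28). The fall in HSC identity did not hold throughout. In WT cells of mosaic mice the list mean was 0.26 unirradiated and 0.40 in losers in replicate 1, and 0.71 and 0.37 in replicate 2. S phase (0.16, adjusted p = 0.00144) had adjusted p = 0.497 with an estimated correlation, G2 and mitosis (0.38, 0.000157) and erythroid genes (0.52, 0.000237) had adjusted p = 0.533 with an estimated correlation, and oxidative phosphorylation (0.18, 0.00144) and B lineage genes (0.42, 0.00144) had adjusted p = 0.56 with an estimated correlation. Granulocyte and monocyte markers had a median of 0.56 (0.00 and 1.53 within replicates, adjusted p = 0.00234) and ribosomal proteins -0.16 (0.03 and -0.34, adjusted p = 0.0105), with adjusted p = 0.663 with an estimated correlation. This average also takes in the Eif2s3y differences given above for the irradiation contrasts. Limma's 0 calls stood beside 483 probes at an unadjusted p under 0.05 (143 without unirradiated WT replicate 2 to 2054 without unirradiated mp53 replicate 2). Without replicate 2 of unirradiated mp53 cells it called Pias1 (difference 2.18, adjusted p = 0.0352), and without its replicate 1 the class II gene H2-Ea (adjusted p = 0.0133), which was not detected in the irradiated groups.

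For averaged competition (4 arrays from mosaic mice against 4 from mice that were not mosaic), B lineage markers had a median of 0.42 (1.01 and -0.28 within replicates, adjusted p = 1.24e-05), macrophage and dendritic cell markers 0.14 (0.60 and 0.04, adjusted p = 0.0191) and stromal and endothelial markers 0.24 (0.39 and 0.03, adjusted p = 0.031, 0.0847 with the table as a block), all with adjusted p = 0.545 with an estimated correlation. HSC identity had -0.21 (-0.60 and 0.06, adjusted p = 0.00367, adjusted p = 0.954 with an estimated correlation), which averages opposite medians of 0.70 for loser against non-competing WT and -0.91 for winner against non-competing mp53. In place of 4 lists, 1 was called without non-competing WT replicate 1, winner replicate 1 or loser replicate 2, 2 without non-competing WT replicate 2 and 7 without non-competing mp53 replicate 2. Limma had 106 probes at an unadjusted p under 0.05 (65 without winner replicate 1 to 222 without non-competing mp53 replicate 2), and 0 list members passed adjusted over the list alone.

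Over all 14 comparisons the p53 target median ranged from -0.17 to 0.34 and the list passed in none (adjusted p from 0.192 to 0.978), nor did senescence and cell cycle inhibitors, whose lowest adjusted p was 0.0682.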

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

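The tests of mature-cell RNA below, within tables and pooled, were chosen after the result was seen, and the brightness covariate and the fit without the 2 dimmest arrays were added as alternatives after the data were seen. Each list here was singled out because the change that went with competition, or with irradiation, differed between the genotypes by an interaction test with camera at the preset correlation.

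For competition by genotype, HSC identity (1.51), Myc targets and ribosome biogenesis (0.76) and ribosomal proteins (0.48) had positive medians, so that losers stood higher relative to non-competing WT cells than winners did relative to non-competing mp53 cells. Negative medians were found for G2 and mitosis (-1.20), immediate early genes (-0.77), NF-kB and inflammation (-0.85), erythroid (-1.58), granulocyte and monocyte (-4.22), B lineage (-1.63), macrophage and dendritic cell (-0.98) and progenitor genes (-2.14). With an estimated correlation the adjusted p was 0.301 for Myc targets, 0.316 for ribosomal proteins and immediate early genes, and 0.287 for the other 8 lists. With the table as a block, immediate early genes had an adjusted p of 0.052. Macrophage and dendritic cell markers went opposite ways within the replicates (-2.06 and 0.14).

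For irradiation by genotype in mosaic mice, medians were positive for G2 and mitosis (1.06), NF-kB and inflammation (0.79), erythroid (1.15), granulocyte and monocyte (2.45), B lineage (1.55), macrophage and dendritic cell (1.63) and progenitor genes (2.28), and negative for HSC identity (-1.43) and ribosomal proteins (-0.34). With an estimated correlation the adjusted p was 0.513 for ribosomal proteins and for granulocytes and monocytes and 0.466 for the other 7. G2 and mitosis (1.78 and -0.03), erythroid (2.24 and -0.06) and granulocyte and monocyte genes (4.99 and -0.84) went opposite ways within the replicates. With the brightness covariate these had -0.68, -0.0771 and -0.88, and without the 2 dimmest arrays G2 and mitosis had -0.13. Under median scaling NF-kB and inflammation, erythroid and B lineage genes had -0.25, -0.26 and -0.84, where the median of all probes was -1.34. With the table as a block, macrophage and dendritic cell markers had an adjusted p of 0.0875.

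The pattern weighed is the lower HSC identity and the higher mature-cell transcripts of winners against losers. Mature blood cell RNA in the sorted samples is a candidate explanation: over the 10 arrays outside the winner group, HSC identity and mature-cell list means correlated at r = -0.813 (permutation p = 0.00137 with 100000 resamples, rho = -0.879 with permutation p = 0.00171, r = -0.867 over 8 arrays without the 2 farthest), within the 5 arrays of each table at -0.848 and -0.929 (exact permutation p = 0.1 and 0.0333), and centred within tables at -0.781 (exact permutation p = 0.00306). The gate on lineage-negative, CD48-negative cells is meant to remove such cells, and no test argued against them as a source. Brightness as a cause could not be decided. The HSC identity list mean difference was -1.05 (SE 0.505, 5 residual degrees of freedom) with the covariate and -1.46 (SE 0.388) without. Its error spans the 0.731 set as the limit. With the covariate HSC identity kept its call at the preset correlation (median -0.92), while the granulocyte and monocyte and erythroid lists lost theirs. Winner replicate 1 had -0.90 at a log2 brightness of 8.01 and unirradiated WT replicate 1 had 0.26 at 8.05, a single pair of arrays. Differentiation of winner cells, a biological difference that goes with competition and genotype in this design, stays open and was not tested. The correlations do not tell it from mature-cell RNA, because sorted cells that vary in differentiation would give them too.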

How the results depend on the processing

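The authors' intensities with the block, leaving out the 2 dimmest arrays and the brightness covariate were chosen after the data were seen, as was applying each alternative to the lists called; the authors' intensities without the block were not run. Of 94 called lists, 94 kept direction and call with the trended and robust prior, 92 each with array weights, without background correction and with all probes of a gene averaged, 88 with the table as a block, 86 with separate normalization and without the filter, 84 with the authors' intensities, 81 without the 2 dimmest arrays, 75 with the brightness covariate, 68 with median scaling and 42 with the strict filter (9 others lost the call), but 0 with an estimated correlation or by fry. On the dimmest array the 95th percentile of raw intensity was 82.3. With the strict filter, which keeps 3998 probes, limma also called 0 in each comparison (17 to 584 at an unadjusted p under 0.05). Its smallest adjusted p was 0.0574 for winner against loser (0.292 otherwise) but 0.438 for irradiation by genotype (0.301 otherwise). Whether low signal limits the single genes is therefore not decided. The causes of the changes below were not tested, except that the strict filter keeps fewer genes per list and leaving out arrays leaves fewer samples, where a lone array is assumed to vary like the other groups.

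Replicate block: arrays of one number share only that number by the labels. Of 15 pairs of groups, 14 had deviations from the group mean that correlated over 0.1 between same-numbered arrays (lowest 0.0566, highest 0.643, median 0.526). All 12 arrays correlated best with an array of their own number, a hint from the data and not the design. With the block, limma called 0 genes in each of the 14 comparisons, as without it, while probes at an unadjusted p under 0.05 numbered 1357 for loser against non-competing WT, 760 for winner against non-competing mp53, 3552 for winner against loser, 1715 for mp53 against WT unirradiated and 290 irradiated without competition, 566 and 1279 for irradiation in non-competing WT and mp53, 1357 and 3614 in WT and mp53 of mosaic mice, 2054 for competition by genotype, 3940 for irradiation by genotype, and 610, 1081 and 251 for mp53, irradiation and competition averaged.

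No background correction: Kit, mp53 against WT unirradiated, 1.90e-04 (-0.01 otherwise).

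Median scaling leaves a shift common to all genes, so a turn under it says nothing about a list or gene relative to the other probes: the median of all probes was 0.47 for loser against non-competing WT, -0.22 for winner against non-competing mp53, -0.72 for winner against loser, 0.68 for mp53 against WT unirradiated, -0.24 irradiated without competition, 0.41 for irradiation in non-competing WT, 0.68 in WT and -0.69 in mp53 of mosaic mice, 0.64 for competition by genotype and -1.34 for irradiation by genotype. It gave 5 lists for loser against non-competing WT, 1 for mp53 against WT unirradiated, 2 for irradiation in non-competing mp53 and 2 for irradiation in WT of mosaic mice. List medians that turned were erythroid 0.13 (loser against non-competing WT), ribosomal proteins 0.12 (irradiation in non-competing WT), NF-kB and inflammation 0.12 (irradiation in WT of mosaic mice), immediate early genes 0.26 (competition by genotype), and NF-kB and inflammation -0.25, erythroid -0.26 and B lineage -0.84 (irradiation by genotype). Genes that turned, some of them not detected in a group so that the fitted value gives no more than its sign, were Aurkb 0.19, Nfkb2 0.15, Rhag 0.13 and Mdm2 -0.24 (loser against non-competing WT), Mdm2 4.06e-04 (winner against non-competing mp53), Ndc80 -0.76, Ermap -0.20, Thy1 -0.48 and Cdkn2c -0.12 (winner against loser), Slamf1 0.84 and Cd48 0.00294 (mp53 against WT unirradiated), Cxcr4 -0.00266 and Slamf1 -0.41 (mp53 against WT irradiated without competition), Nfkb2 0.39 (irradiation in WT of mosaic mice), Ndc80 -0.74 and Cd79a -0.68 (irradiation in mp53 of mosaic mice), Ndc80 0.21 (competition by genotype), and Ndc80 -1.73, Aurkb -0.77, Rps15a -1.48, Fcrla -0.76, Il7r -0.33 and Mrc1 -0.69 (irradiation by genotype).

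The authors' intensities with the block gave 1 list for averaged competition. No detection filter gave 1 gene, Acsl4 (adjusted p = 0.0212), and 17 lists for winner against loser, 2 lists for mp53 against WT irradiated without competition, 2 for irradiation in non-competing mp53 and 0 for irradiation in WT of mosaic mice. The strict filter gave 5 lists for loser against non-competing WT, 6 for winner against non-competing mp53, 5 for winner against loser, 1 for irradiation in non-competing mp53, 5 for irradiation in mp53 of mosaic mice, 5 for competition by genotype, 4 for irradiation by genotype, 1 for mp53 averaged, 5 for irradiation averaged and 1 for competition averaged. The trended and robust prior gave 3 genes for winner against loser, Ndn (-4.34) and, not detected in losers, Klra9 and Rasgrp3, and 2 lists for irradiation in WT of mosaic mice.

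Camera with an estimated correlation gave 0 lists in the 12 comparisons with calls. Fry gave 0 in 11 of them and 1 for irradiation in non-competing WT.

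Without the 2 dimmest arrays there were 5 lists for loser against non-competing WT and 1 for mp53 against WT unirradiated. Oxidative phosphorylation had -0.00783 (irradiation in mp53 of mosaic mice) and G2 and mitosis -0.13 (irradiation by genotype). Mdm2 had -0.0540 and Ccng1 -0.32 (loser against non-competing WT), Ccng1 0.23 (winner against loser), and Mdm2 -0.0335 and Ccng1 -0.15 (mp53 against WT unirradiated).

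The brightness covariate gave 1 list for mp53 against WT unirradiated, 8 for irradiation in non-competing WT, 1 for irradiation in non-competing mp53, 4 for irradiation in WT of mosaic mice and 7 for irradiation in mp53 of mosaic mice. G2 and mitosis had -0.0750 (winner against loser), oxidative phosphorylation -0.0613 and granulocyte and monocyte -0.0114 (irradiation in mp53 of mosaic mice), and G2 and mitosis -0.68, erythroid -0.0771 and granulocyte and monocyte -0.88 (irradiation by genotype). Ccng1 had 0.31 (winner against loser), and Ccng1 0.0113 and Slamf1 -0.00887 (mp53 against WT irradiated without competition). Slamf1 was detected on at most 3 arrays, so its turn here shows no measured change.

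Leaving out each array in turn, genes called ranged from 0 to 1 for irradiation in non-competing mp53, 0 to 599 for irradiation in mp53 of mosaic mice, 0 to 1285 for irradiation by genotype and 0 to 1 for irradiation averaged. Both large counts came without unirradiated mp53 replicate 2, which left the dimmest array as the only one of its group. Lists ranged from 3 to 8 for loser against non-competing WT, 5 to 16 for winner against non-competing mp53, 10 to 14 for winner against loser, 0 to 2 for mp53 against WT unirradiated, 1 to 9 irradiated without competition, 2 to 6 for irradiation in non-competing WT, 0 to 8 in non-competing mp53, 0 to 6 in WT and 6 to 12 in mp53 of mosaic mice, 9 to 14 for competition by genotype, 4 to 11 for irradiation by genotype, 3 to 12 for mp53 averaged, 6 to 10 for irradiation averaged and 1 to 7 for competition averaged.

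Medians and differences whose sign changed when an array was left out ranged as follows. Slamf1 was detected on at most 3 arrays, so its fitted values do not give the size of a change. For winner against non-competing mp53: G2 and mitosis -0.0120 to 0.95, granulocyte and monocyte -0.00500 to 4.11, T and NK -0.0780 to 0.90, Glrx -0.10 to 1.498, Klrd1 -0.15 to 2.06, Mdm2 -0.26 to 0.13 and Ccng1 -0.00741 to 0.18. For mp53 against WT irradiated without competition: G2 and mitosis -0.61 to 0.31, HSC identity -0.18 to 0.82, granulocyte and monocyte -3.56 to 0.23, Ttk -1.11 to 0.10, Ltf -6.37 to 0.22 and Kit -0.98 to 0.62. For irradiation in mp53 of mosaic mice: oxidative phosphorylation -0.00783 to 0.63. For loser against non-competing WT: Mdm2 -0.22 to 0.27, Ccng1 -0.32 to 1.09, Kit -0.65 to 0.94 and Slamf1 -0.0419 to 1.36. For winner against loser: Ccng1 -1.17 to 0.23. For mp53 against WT unirradiated: Mdm2 -0.0335 to 0.34, Ccng1 -0.15 to 1.19 and Kit -0.51 to 0.48. For irradiation in non-competing WT: Rpl22 -1.13 to 0.00260 and Hbb-b2 -0.0527 to 4.23.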

Other observations

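The tests of the Y-linked transcripts and the splits within tables were chosen after the result was seen.

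Sex-linked transcripts differed between arrays of the same group. The Y-linked Eif2s3y, a translation initiation factor gene, stood at 8.70 and 4.23 log2 in replicates 1 and 2 of unirradiated WT cells, 8.98 and 4.22 in unirradiated mp53 cells, 9.43 and 8.69 in non-competing WT cells, 4.23 and 7.95 in non-competing mp53 cells, 4.33 and 6.95 in losers and 8.77 and 7.89 in winners. Xist, the RNA that silences an X chromosome in female cells, stood at 8.11 and 6.58 in losers and 6.36 and 5.27 in winners. It had 4.88 and 5.20 in non-competing WT cells and 7.94 and 5.64 in non-competing mp53 cells. In unirradiated WT (6.47 and 6.55) and mp53 cells (6.18 and 6.28) Xist was level between replicates, where Eif2s3y was not.

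In replicate 1, Eif2s3y was thus detected in winners and not in losers, and Xist lay lower in winners (difference -1.75), although the populations carry the same replicate number. Loss of the Y-linked signal on a dim array is argued against by the dimmest array, where Eif2s3y was at 8.98, with the lowest detected value at 5.04. Whether the populations of replicate 1 came from the same animals stays open. The test took the smallest difference over the 3 Y-linked transcripts (-0.0340), but 2 of them were never over 1 log2 above the lowest detected value, so it could not have come out otherwise and excludes nothing. The remaining transcript, Eif2s3y, is the one that defines the pattern, and in unirradiated mosaic mice it stood close in mp53 and WT cells of the same number (8.98 and 8.70, 4.22 and 4.23). No biological explanation was tested.

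For the averaged comparisons, other splits of the same arrays were counted. For the lists of mp53 against WT, 21 of 100 splits gave as many as the real 8 (highest other 14, and 0 for the split by table), and for those of irradiation 27 of 100 gave as many as the real 8 (highest other 14), so chance is not excluded for either. These splits mix the tables and were fitted without the block. With arrays exchanged within their table only and the table as a block, 12 of 32 splits gave as many as the real 8 lists for mp53 (highest other 15) and 30 of 81 as many as the real 8 for irradiation (highest other 13), which does not exclude chance either. For competition, the 18 splits are too few for a share under 0.05 (13 gave as many as the real 4 lists, highest other 11), as are the 8 within tables (7 gave as many as the real 3, highest other 11). Median list counts of the other splits were 3, 4 and 6 for mp53, irradiation and competition, and 5, 5 and 7 within tables. The counts of genes say nothing about chance, because limma called 0 in each real split (304, 483 and 106 probes at an unadjusted p under 0.05) and every split reaches 0: 100 of 100 for mp53, 100 of 100 for irradiation and 18 of 18 for competition. Their highest other counts were 1843, 6 and 0. The 1843 came from the split by deposited table, which points to a structure of the samples by table, and with the table as a block the real count for mp53 was also 0.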
